A study of Gallus gallus with 12 samples.

How the data were processed

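RNA was sequenced from interdigital region 3 of the chicken hindlimb, the tissue between forming digits that is removed by programmed cell death. Per the labels' protocols, beads were implanted at Hamburger-Hamilton stage 30 and the tissue was collected 12 h later. The beads carried either Noggin, a secreted protein that binds bone morphogenetic proteins (BMPs) and blocks their signalling, or phosphate-buffered saline (PBS) as the control. The design text places the 2 kinds of bead in opposite limbs. Libraries were made from 180 ng of total RNA with Lasy-Seq version 1.1, per the labels' protocols. Lasy-Seq is a multiplexed method that adds sample barcodes during reverse transcription and reads transcript ends, so that gene length is not expected to scale the values. The submitters' processing notes name fastp 0.21.0, BWA 0.7.17-r1188 and Salmon. The genome build, the annotation release, the counting options and any use of molecular identifiers are not given in the sources used here.

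One table with 30108 gene rows and 12 library columns was analysed. Although it was deposited as a table of counts, its values are on a natural log scale: the exponential of each value minus 1 added up to 1000000 in every column. The deposited values were therefore read as the natural log of (CPM, the reads of a gene per 1000000 reads, plus 1). After the log was undone, all values above 0 were whole multiples of the value of 1 read in their column, within a tolerance of 0.001 read. This gave the number of reads behind every value. The recovered totals were 1624309 to 3513398 reads per library. A count of 0 allows up to 0.854 CPM in the deepest library and 1.85 CPM in the shallowest, taking 3 reads as the limit, and this covers counting error only.

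Gene rows carry Ensembl chicken gene identifiers and no symbols. The reference gene table used here holds no Ensembl identifiers (its column for them is empty), so 0 could be looked up, which says nothing about the identifiers themselves. No gene is therefore named by symbol, position or function. For that reason 32 gene lists (831 genes, covering BMP targets, oxidant-producing and antioxidant enzymes, cell death, limb patterning, cell cycle and other cell types), written before the data were examined, could not be tested. The rule for named genes, fixed at the same time, took genes with a symbol past the threshold, ranked by fold change, with a mean of at least 5 CPM. With no symbols, it was reduced to the 2 highest and 2 lowest fold changes, printed by identifier.

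Libraries were assigned to 6 Noggin and 6 PBS replicates from the sample titles, and table columns to libraries through the library codes in the labels. The design had named a test for counts. Because the values are log CPM, limma 3.58.1 in R 4.3.3 was used instead, on log2(CPM + 1), with a mean-variance trend and robust variance shrinkage. The robust option, the scaling and the low-count filter were kept from that design, and the pseudocount of 1 was chosen once the unit was known. CPM were rescaled by trimmed means of M-values (TMM), written out directly, with 30% of the log ratios and 5% of the mean levels trimmed. The factors lay between 0.981 and 1.03. Genes entered the test if they reached 4.23 CPM (10 reads at the median depth) in at least 6 libraries and 15 reads in total. This kept 10574 genes holding 98.9% of the reads. The model held the group alone, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of weakly expressed genes. Differences of single values between groups were tested by exact two-sided permutation of the group labels, without regard to the replicate number.

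The same steps were tested on simulated data, with reads drawn for the 10574 genes at the real depths and 200 genes changed in the 6 against 6 design. Each gene took its within-group spread from a trend over mean expression in the real libraries, grouped as labelled. The libraries numbered 6, taken up in the results, were part of that spread. The test recovered 38% of genes changed by 0.5 on the log2 scale, 78% of those changed by 1, 92% of those changed by 1.5 and 100% of those changed by 2. There were 4 false calls among 158. Libraries were drawn independently, with no effect of the replicate number and no exchanged labels, so these rates need not hold for the real libraries.

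Alternatives were another scaling (median of ratios, upper quartile, none), another low-count filter, another pseudocount, limma-voom on the recovered reads, the replicate number as a block, and leaving out single libraries or both libraries of a number. No 2 libraries were duplicates: the chi-square of their reads per degree of freedom was at least 2.78 over the 66 pairs. Nothing in the labels says that each library came from a separate embryo, so p-values measure the spread between these samples. All columns of the table were used. The negative binomial tests of the design were not used on this table of log values, although reads were recovered from it, and limma-voom was the only test run on those reads.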

Results

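A total of 12 transcript-end RNA-seq libraries were compared, 6 from interdigital tissue that had held a Noggin bead for 12 h and 6 from tissue that had held a PBS bead. Depth was 2606000 ± 626300 reads in the Noggin group and 2145000 ± 432900 reads in the PBS group (mean ± SD, n = 6 each, exact two-sided permutation p = 0.167). Between 16487 and 18727 genes had at least 1 read per library. The most abundant gene took 3.4% to 6.21% of the reads, with no difference past the threshold between groups (exact permutation p = 0.474).

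The comparison of Noggin with PBS asks which transcripts of the interdigit depend on BMP signalling, within a study of reactive oxygen species and interdigital cell death. As labelled, 13 of 10574 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), of which 6 were higher and 7 lower with Noggin. None of the 6 rose by more than 2-fold, and 4 of the 7 fell by more than 2-fold. The median size of the 13 changes was 0.83 on the log2 scale. The fit that gave the 13 genes did not pair libraries by replicate number. With the replicate number as a block, 0 genes passed (limma, 1382 at an unadjusted p below 0.05). Without the block, 1464 genes lay below an unadjusted p of 0.05, against 529 expected by chance. In 29 genes every Noggin library lay above every PBS library, and in 17 genes below. Chance alone gives a separation for 0.216% of genes, or 22.9 genes, counting both directions together.

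Genes are given by identifier, since the table does not pair identifiers with symbols. Among those of the 13 genes with a mean of at least 5 CPM, the largest rises were those of ENSGALG00010003189 and ENSGALG00010027912. ENSGALG00010003189 stood at 34.6 ± 6.82 CPM with Noggin and 18.3 ± 6.95 CPM with PBS (mean ± SD, n = 6 each). Its log2 fold change was 0.95 ± 0.19 (SE, adjusted p = 0.043 by limma), and Noggin was the higher library in 5 of the 6 replicate numbers. ENSGALG00010027912 stood at 58.2 ± 10.3 CPM with Noggin and 33.3 ± 9.06 CPM with PBS, a log2 fold change of 0.83 ± 0.16 (adjusted p = 0.0337 by limma), also with Noggin higher in 5 of the 6 numbers. The largest falls were those of ENSGALG00010011187 and ENSGALG00010027958. ENSGALG00010011187 averaged 3.4 ± 1.26 CPM with Noggin and 13.4 ± 5.59 CPM with PBS, and its log2 fold change was -1.63 ± 0.30 (adjusted p = 0.0337 by limma). ENSGALG00010027958 averaged 4.78 ± 2.23 CPM with Noggin and 13.6 ± 3.57 CPM with PBS, and its log2 fold change was -1.38 ± 0.27 (adjusted p = 0.0337 by limma). Both falls had the same direction in 6 of the 6 replicate numbers, but in number 6 the values were low. There ENSGALG00010011187 stood at 4.11 CPM in the library labelled Noggin 6 and 4.75 CPM in that labelled PBS 6, which are close. ENSGALG00010027958 stood at 5.65 and 9.93 CPM. In these libraries 1 read is 0.514 and 0.432 CPM. With the replicate number as a block, these 4 genes had adjusted p-values of 0.0968 to 0.139 by limma. With limma's robust option off, 0 genes passed (1486 at an unadjusted p below 0.05), while limma-voom on the recovered reads called 16. Leaving out any 1 of the 10 libraries numbered 1 to 5 gave 0 genes by limma and by limma-voom (1185 to 1345 at an unadjusted p below 0.05), whereas 530 genes passed without the library labelled Noggin 6 and 669 without the library labelled PBS 6.

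**Figure D1:**
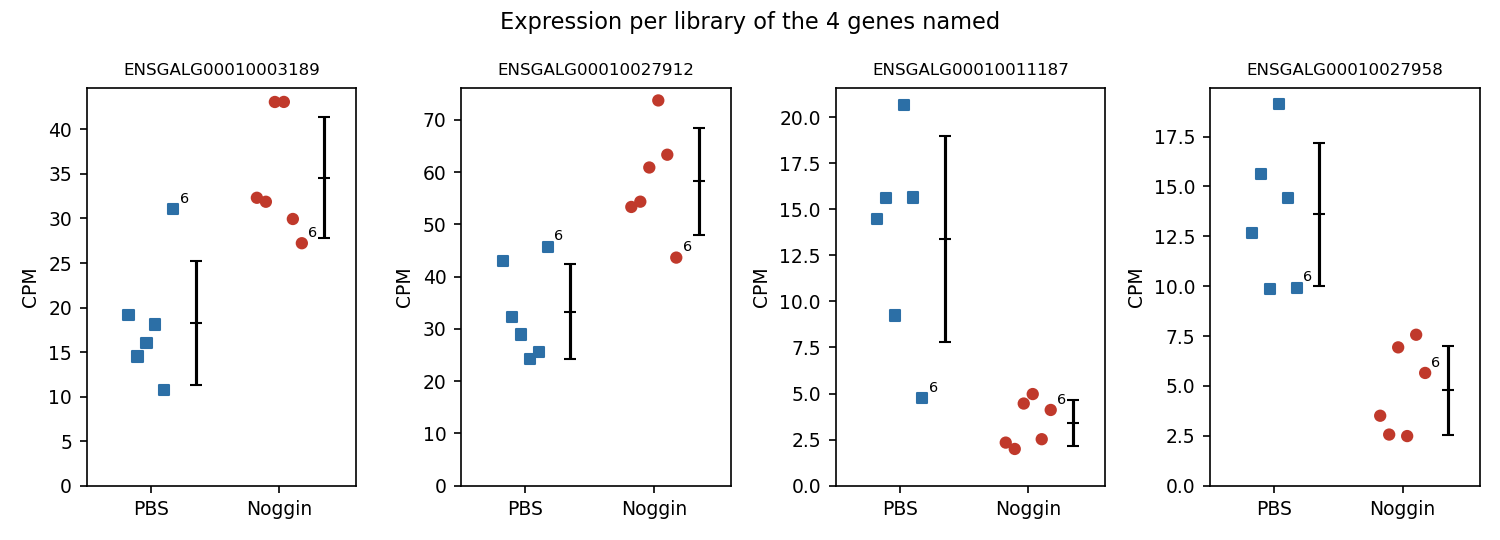
CPM per library of the 2 genes with the largest rise and the 2 with the largest fall among the genes past the threshold as labelled, with squares for libraries labelled PBS, circles for libraries labelled Noggin, bars for the mean ± SD (n = 6) and a mark on the libraries numbered 6. In ENSGALG00010003189 the library labelled PBS 6 stood at 31.1 CPM and the library labelled Noggin 6 at 27.2 CPM.

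The libraries fell into 2 sets along the main axis of variation, and these sets matched the labels except at replicate number 6. The first principal component of the 500 most variable genes held 42.1% of the variance. The libraries labelled Noggin 1 to 5 lay between 13.04 and 15.07 on it, and those labelled PBS 1 to 5 between -19.6 and -9.25. The library labelled Noggin 6 lay at -12.2 and the library labelled PBS 6 at 14.5. The group means differed by 18.9 on this axis (9.42 ± 10.6 against -9.42 ± 12.2, SD, n = 6 each, exact permutation p = 0.0346). The permutation did not keep libraries of the same replicate number together, so differences within numbers were not tested. Across the tested genes, the library labelled Noggin 6 correlated with the Noggin libraries 1 to 5 at a mean r of 0.935 and with the PBS libraries 1 to 5 at 0.947. The library labelled PBS 6 correlated with them at 0.956 and 0.928. These correlations are across genes, which are not independent replicates. The second component, with 19.1% of the variance, set both libraries numbered 2 and both numbered 6 (12.4 to 14.4) apart from the other 8 (-8.25 to -5.75).

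**Figure D2:**
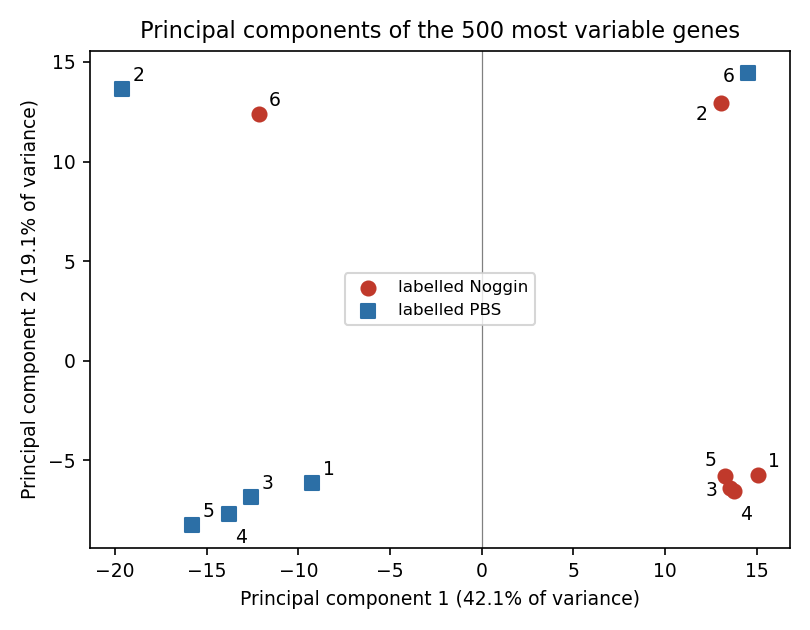
Principal component 1 against principal component 2 (scores on log2(CPM + 1), unitless) for the 12 libraries, marked with their replicate numbers, circles for libraries labelled Noggin and squares for those labelled PBS. On component 1 the libraries labelled PBS 6 (14.5) and Noggin 6 (-12.2) each lie among those of the other group.

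The comparison was therefore repeated without the 2 libraries numbered 6, a choice made after their values were seen. In replicate numbers 1 to 5, 1130 of 10574 genes (10.7%) passed the adjusted p of 0.05 (limma), of which 713 were higher and 417 lower with Noggin. The median change was 0.69 on the log2 scale (quartiles 0.45 and 1.07). Changes of more than 2-fold were found in 173 genes that rose and 157 that fell, and changes of more than 4-fold in 25 that rose and 19 that fell. The largest rise was 4.95 and the largest fall -4.53 on the log2 scale. In 602 genes every Noggin library lay above every PBS library and in 380 genes below. Chance gives 0.794% of genes, or 83.9 genes, counting both directions together. Adding the replicate number as a block gave 1498 genes in numbers 1 to 5 (limma), 934 higher and 564 lower with Noggin. The adjusted p-values of both fits do not allow for the choice of the libraries left out. Leaving out both libraries of any one of the numbers 1 to 5, with number 6 kept, gave 0 genes each time by limma and by limma-voom (997 to 1111 genes at an unadjusted p below 0.05).

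All 13 genes called as labelled were among the 1130, with the same direction. The fit of numbers 1 to 5 reuses libraries that gave the 13, so this overlap is no independent support. Without number 6, ENSGALG00010003189 stood at 36.1 ± 6.47 CPM with Noggin and 15.7 ± 3.32 CPM with PBS (SD, n = 5 each), a log2 fold change of 1.18 ± 0.18 (SE, adjusted p = 1.43e-05 by limma). ENSGALG00010011187 averaged 3.26 ± 1.36 CPM with Noggin and 15.1 ± 4.08 CPM with PBS, a log2 fold change of -1.92 ± 0.29 (adjusted p = 1.1e-05 by limma). ENSGALG00010027912 stood at 61.1 ± 8.22 CPM with Noggin and 30.8 ± 7.5 CPM with PBS (adjusted p = 7.82e-06 by limma). The log2 fold change of ENSGALG00010027958 was -1.51 ± 0.29 (adjusted p = 0.000421 by limma). Over the 1130 genes, the fold change as labelled was 71.8% of that in numbers 1 to 5 at the median.

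The changes in numbers 1 to 5 reached the abundant genes. Of 1212 genes with a mean of at least 100 CPM, 288 (23.8%) passed, 218 of them higher and 70 lower, with a median change of 0.37 on the log2 scale. Of 2215 genes below 10 CPM, 151 (6.82%) passed, 74 higher and 77 lower, with a median change of 1.28. The standard errors differed accordingly, with medians of 0.09 and 0.31, so small changes of weakly expressed genes were not detectable at this depth. Among the abundant genes, 11 of the 218 rose by more than 2-fold and 18 of the 70 fell by more than 2-fold. The share of higher calls was 63.1% over all 1130 genes and 58.1% under median-of-ratios scaling, with totals of 1087 to 1156 genes across the scalings, pseudocounts and limma-voom.

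**Figure D3:**
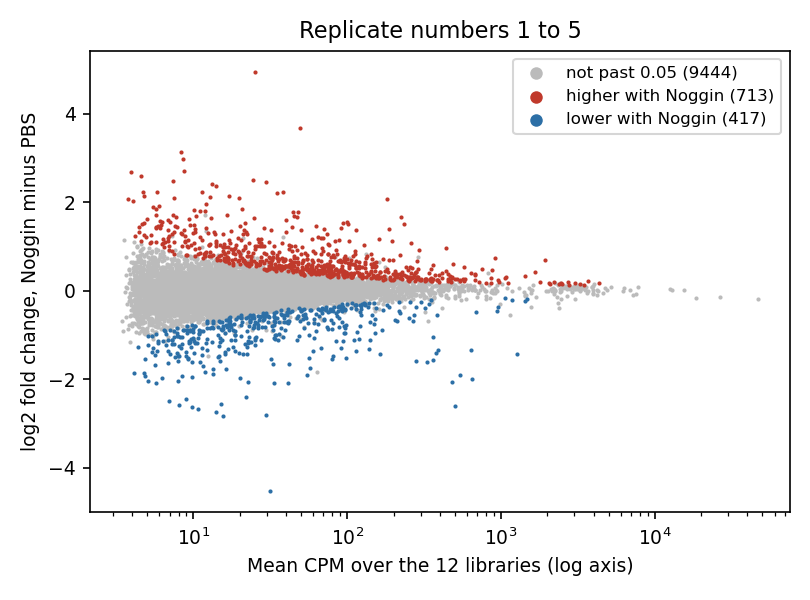
Log2 fold change of Noggin against PBS in replicate numbers 1 to 5 (y axis) against the mean CPM over the 12 libraries (x axis, log scale), 1 point per tested gene. The 713 genes higher and 417 genes lower with Noggin past an adjusted p of 0.05 are coloured.

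The direction of these changes was then read in libraries that had not been used to call them. For each of the numbers 1 to 5, genes were called in the other 4 of these numbers, which gave 813 to 981 genes. Between 92.4% and 95.2% of them had the same direction in the number held out. Numbers 1 to 5 were set apart after the libraries numbered 6 were seen to lie with the other group, which favours agreement among them. The low-count filter and the scaling had also used all libraries, those held out included. For number 6, 143 of the 1130 genes called in numbers 1 to 5 (12.7%) had the same direction between the libraries as labelled, and 987 (87.3%) the opposite one. Placed between the PBS mean (0) and the Noggin mean (1) of the other libraries, held-out libraries labelled Noggin 1 to 5 lay at 0.86 to 0.886 and those labelled PBS 1 to 5 at 0.0493 to 0.28. The library labelled Noggin 6 lay at 0.214 and the library labelled PBS 6 at 0.884.

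**Figure D4:**
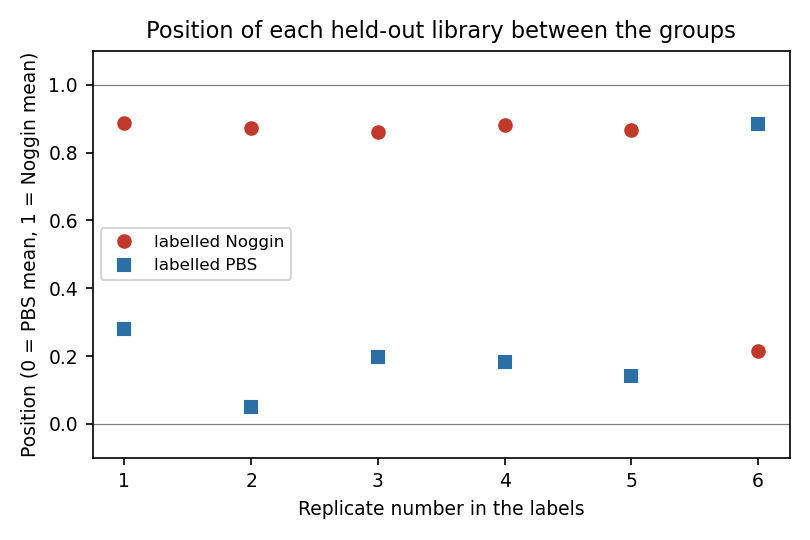
Position of each library between the PBS mean (0) and the Noggin mean (1) of numbers 1 to 5 over all tested genes (unitless), with the library's own number left out of the means, by replicate number. The libraries labelled Noggin 6 (0.214) and PBS 6 (0.884) lie within the range of the other group.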

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

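The tests of the libraries numbered 6 were chosen after the result was seen, and so was the set of numbers 1 to 5 whose splits were counted. Of 20 groups of 6 library values examined for a single distant library, 4 held one, where chance gives about 1 in 20. All 4 concern the 2 libraries numbered 6 on 2 related measures. They are not independent of each other, so their number is not weighed against the chance rate. On the first principal component, the library labelled Noggin 6 (-12.2) stood apart from the other Noggin libraries and the library labelled PBS 6 (14.5) from the other PBS libraries. The same 2 libraries stood apart in their position between the PBS and Noggin means, at 0.214 and 0.884.

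A lack of response to the Noggin bead in number 6 would leave its 2 libraries alike, with a slope of their difference on the mean change of numbers 1 to 5 near 0. The slope was -0.799, against 0.736 to 0.999 for each of the numbers 1 to 5 when held out, which argues against that explanation. Low depth is also argued against, since the shallower library numbered 6 held 1946971 reads and the shallowest of the others 1624309. Both libraries numbered 6 lay with the opposite group, and 87.3% of the genes called in numbers 1 to 5 had the opposite direction there, which is consistent with an exchange within number 6. A reversed response in that tissue and the step of any exchange stay open: the sample list gives PBS before Noggin for number 6 and Noggin before PBS for the other 5 numbers, the library codes run Noggin then PBS for all 6, and this order assigns no library.

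Of 100 splits of the 12 libraries into 6 and 6 (from 462 possible), 3 called as many genes as the 13 of the labelled split, that one included. This lies under the limit of 5 of 100 set beforehand, but the splits ignore the replicate number. With that number as a block 0 genes passed, so chance is not excluded for the 13 genes. The highest other split drawn called 74 genes, several times the real count, which points to a structure of the samples that involves number 6: it has PBS 6 on the Noggin side in place of Noggin 3. The exchange of the labels within number 6, not among the splits drawn, called 1257 genes (1255 by limma-voom), and the exchange within any other number 0 by limma and limma-voom (342 to 482 at an unadjusted p below 0.05). Of 100 splits of the 10 libraries numbered 1 to 5 (from 126 possible), 1 called as many genes as the real one with its 1130, and the highest other split called 2. Among the splits drawn, only the labelled division of those 10 libraries called more than 2 genes. Number 6 was left out after its libraries were seen to lie with the other group. That choice favours the labelled division, so no chance level is drawn from this count.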

How the results depend on the processing

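The added alternatives (leaving out both libraries of a number, alone or with the block or limma-voom, other pseudocounts, no rescaling, limma without its robust option) were chosen after seeing the data. As labelled, the count of 13 genes (6 higher, 7 lower) stayed at 11 to 16 under median-of-ratios, upper-quartile and no rescaling, a stricter filter, a pseudocount of 0.5 and limma-voom. Without a low-count filter it was 21 genes (11 higher), and with a pseudocount of 4 it was 32 genes (22 higher). Without limma's robust option it was 0 genes in either direction (1486 at an unadjusted p below 0.05), and the cause was not tested. Leaving out 1 library gave 0 to 669 genes (0 to 438 higher, 0 to 231 lower). Leaving out any of the 10 libraries numbered 1 to 5 gave 0 by limma and limma-voom (1185 to 1345 genes at an unadjusted p below 0.05), leaving out the library labelled Noggin 6 gave 530 (552 by limma-voom) and the library labelled PBS 6 669 (726 by limma-voom). Leaving out both libraries numbered 1, 2, 3, 4 or 5 gave 0 genes by limma and limma-voom, 0 higher and 0 lower (997 to 1111 at an unadjusted p below 0.05). Leaving out both numbered 6 gave 1130 genes (713 higher, 417 lower), or 1154 (714 higher, 440 lower) by limma-voom. The difference on the first principal component was 23.7 with 2000 genes and 28.7 with all tested genes, past 0.05 both times. The 4 named genes kept their direction in all 119 values under these alternatives, the block included, and lost the threshold in 70, and with 1 library left out 8 of 48 values stayed past it. Under the stricter filter ENSGALG00010011187 was not among the genes tested. At this depth 38% of simulated changes of 0.5 on the log2 scale were recovered.

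The replicate numbers were not taken as pairs, because over all tested genes deviations from the group means did not correlate above 0.1 for every number. The lowest value was -0.24, for number 6, but an exchange there would itself lower it. Number 3 lay at 0.0779. Over genes of at least 20 CPM the lowest was -0.183. With the replicate number as a block, 0 genes passed as labelled by limma, with 0 higher and 0 lower (1382 at an unadjusted p below 0.05). With the block and without number 6, 1498 genes passed (934 higher, 564 lower). In numbers 1 to 5 the same-numbered correlations were 0.0805 to 0.283 and the others at most 0.0114, and over genes of at least 20 CPM they were 0.17 to 0.516 and at most 0.0621. Over the 3188 genes of at least 20 CPM with p above 0.2 in numbers 1 to 5 they were 0.251 to 0.478, with number 6 at 0.478, others reached 0.448, and 12 of 12 libraries correlated best with their own number. Without the genes that set numbers 2 and 6 apart they were 0.0888 to 0.292. Over all tested genes 8 of the 12 libraries correlated best with their own number, and in numbers 1 to 5 10 of 10 did, which points to pairing there. The design text sets the beads in opposite limbs without tying a number to an embryo. Planned tests by edgeR and DESeq2 were not run on this table of log values. Tests per transcript, of gene lists and of cell type shares were not run, since the table holds genes with no names.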

Other observations

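The tests in this part were chosen after the patterns were seen. Some genes were present in both libraries of certain replicate numbers and nearly absent from the rest, whichever bead had been used. Among tested genes with a mean of at least 20 CPM, 10 showed a gap of more than 3 on the log2 scale between a high and a low set of libraries. Tested genes had to reach 4.23 CPM in at least 6 libraries. A gene high only in the libraries numbered 2 and 6 and at 0 CPM in the other 8 was therefore not searched. The number of such genes and their low levels depend on this filter. In 9 of the 10, both libraries of every number were on the same side. Of these, 7 genes were high in the 4 libraries numbered 2 and 6, at means of 124 to 598 CPM, and averaged 3.22 to 7.39 CPM in the other 8, which is 1.03% to 2.97% of the high level. The remaining gene, singled out after its values were seen and given without its identifier, was split by treatment in numbers 1 to 5, with 30.7 to 60.9 CPM with Noggin and 0 to 2.89 CPM with PBS. It stood at 0 CPM in the library labelled Noggin 6, where a count of 0 allows up to 1.54 CPM, and at 49.6 CPM in the library labelled PBS 6.

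A candidate explanation for the 7 genes is sex, since female birds carry a W chromosome that males lack and only 1 copy of the Z chromosome, whose genes are incompletely compensated and would be moderately lower in the same libraries. There were 133 genes lower in all 4 libraries numbered 2 and 6 than in all other 8, against 11 to 33 for the 14 other choices of 2 numbers and 21.4 by chance. Their median was -0.72 on the log2 scale (quartiles -0.86 and -0.62). Medians for the other choices ran from -0.82 to -0.39, so the median does not set numbers 2 and 6 apart. Genes higher in all 4 numbered 42, against 10 to 41 for the other choices. The count of lower genes goes with sex as a hypothesis. However, no chromosome could be assigned to these genes and no label ties a number to an embryo. Another difference shared by numbers 2 and 6 stays open. A mix-up of libraries among numbers 1 to 5 is argued against, since 10 of 10 of them correlated best with the library of their own number over all tested genes. One that involves number 6 stays open. With number 6 included 8 of 12 libraries did so over all tested genes, a count that an exchange within number 6 would itself disturb. It was 12 of 12 over the 3188 genes with p above 0.2 in numbers 1 to 5 (limma). It was also 12 of 12 over 3070 of these, without those that set numbers 2 and 6 apart. Both of these counts used deviations from the mean of all 12 libraries, whereas the 8 of 12 used deviations from the group means. Both gene sets were chosen after the data were seen.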
